A study of Mus musculus with 36 samples.

How the data were processed

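The series holds 36 RNA sequencing libraries of mouse hippocampus, prepared from polyadenylated RNA with a TruSeq kit and read on a NovaSeq instrument per the labels. The labels give 6 groups of 6 libraries with 3 females and 3 males each: young (8 months), old (18 months) and old with nanoligomer (18 months) in the C57BL/6 arm, and non-carrier littermates, APP/PS1 and APP/PS1 with nanoligomer (4 months each) in the transgenic arm. The APP/PS1 line, the dose, the duration and the sequence of the nanoligomer are not given in the sources used here.

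The submitters' processing notes name STAR, DESeq2 and the genome mm10, without saying which step each served; the tool that assigned reads to genes, the annotation and all versions are not given in the sources used here. The deposited values are size-factor-normalized counts, a signal that the authors scaled per library within each of 4 tables of 12 libraries and 24421 gene symbols. Whole reads were recovered by dividing the values of each library by their common step: 100% of the values of each library lay within 0.001 reads of a whole number. 12 libraries stand in 2 tables each, and their recovered reads are identical in both. 2349 symbols had no read in any library. All 12 value columns of each table were used, so the number of columns of values left out is 0. The column of treated APP/PS1 male 3 differs from its sample title in 1 letter and was matched as the only one left of its group. Mouse genes and human transgenes of the same name are not separated in the tables. Gene coordinates come from GENCODE annotation of GRCm38.

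Recovered reads gave 27.6 to 46.3 M per library, with 0.913 M in APP/PS1 nanoligomer female 3. Group means were 40.5 M in young, 40.4 in old, 35.9 in treated old, 38.0 in littermate, 36.0 in APP/PS1 and 33.3 in treated APP/PS1 libraries. Transcripts of the ribosomal RNA precursor Rn45s took 0.104 to 0.940% of reads.

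Each comparison was tested within its own table, since tables were normalized apart. Limma 3.58.1 in R 4.3.3 was fitted to log2 of the deposited normalized count plus 1 for genes with a mean of at least 10, with sex and group as factors and an intensity trend. Genes with a Benjamini-Hochberg adjusted p under 0.05 were called. The effect within each sex and the difference between the sexes came from a fit with their interaction. Differences between effects in separate tables with no shared library came from 1 joint limma fit of the 24 libraries with its own mean, sex and group term for each table. Recovered reads were also tested with edgeR 4.0.16 (quasi-likelihood with TMM factors) and DESeq2 1.42.0 (Wald test): edgeR called 6, 0, 8 and 0 genes and DESeq2 called 123, 2, 253 and 7 for age, treatment in old mice, the transgenes and treatment in APP/PS1 mice. Limits of 95% are those of the limma coefficient.

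47 gene lists with 1157 members, 1131 of them in the tables, were fixed beforehand: inflammatory and antiviral pathways, cell types, hippocampal and neighbouring regions, metabolic and stress pathways and controls. 45 of them had at least 5 measured members and were tested with camera at its preset inter-gene correlation of 0.01, with adjustment over the lists; camera with an estimated correlation and fry were run beside it. Fold changes of pairs of comparisons were correlated across genes. As a reference without effects, deviations of whole libraries from the mean of their group and sex were rescaled and dealt anew within sex. Where the pair shared libraries, a second reference used 3 of the shared libraries in each comparison.

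Genes were named by a rule. Nfkb1 and Nlrp3 were named in every comparison, and App, Prnp and Thy1 in those of transgenic mice, whatever their p. Some genes that the rule names are not reported here. Up to 8 genes called higher and 8 called lower were added by smallest p where females and males had the same sign, leaving out predicted and Rik genes, pseudogenes and sex-linked genes. Up to 4 called members of each list, or at most 2 with the smallest p where none was called, were added, and where fewer than 4 genes were called in a comparison, the 4 highest and 4 lowest by p. Groups, tests, lists, this rule and the first set of alternatives were fixed before the data were examined. Alternatives covered the filter, the pseudocount, the scaling, the trend, library weights, the sex term, a block on the replicate labels, the count tools and leaving out each library in turn. Leaving out APP/PS1 nanoligomer female 3, or APP/PS1 female 3, or both, and covariates from marker scores were added after seeing the data.

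The tests were tried on simulated data: counts were drawn from negative binomial distributions with the means, depths and gene-wise dispersions of these libraries, and randomly drawn genes were changed. Of genes changed 1.5-fold, 2-fold and 4-fold, 59.7%, 71.6% and 87.9% were recovered in the age comparison, 40.3%, 76.1% and 92.4% in treated old mice, 34.3%, 61.2% and 95.5% in the transgene comparison and 32.8%, 61.2% and 80.3% in treated APP/PS1 mice without female 3. The share of false calls for these changes ran from 2.01% to 10.6%, and with no gene changed 0 were called in each of the 4. A 4-fold sex difference was recovered for 57.6%, 72.7%, 77.3% and 57.6% of genes, with 5.77%, 8.45%, 11% and 10.2% of calls false. Genes were drawn independently of one another, so variation that real libraries share across genes is missing and these rates may not carry over. Splits of the real libraries of the transgene comparison called up to 190 genes. Figures were drawn with matplotlib 3.10.9 in Python 3.11.15, with numpy 2.4.6 and pandas 2.3.3.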

Results

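RNA sequencing of polyadenylated RNA gave 36 libraries of mouse hippocampus in 6 groups of 6, each with 3 females and 3 males. The aging arm held C57BL/6 mice: young mice of 8 months, old mice of 18 months, and old mice of 18 months treated with a nanoligomer, a short antisense molecule built on a peptide nucleic acid. The transgenic arm held mice of 4 months: non-carrier littermates, APP/PS1 mice, an amyloid transgenic model, and APP/PS1 mice treated with nanoligomer. The series title names NF-kB, the transcription factor family of inflammatory signalling, and NLRP3, the sensor of an inflammasome, as the targets of downregulation. The dose and the length of treatment are not given in the sources used here. Libraries held 27.6 to 46.3 M reads on 24421 gene symbols, with 17358 to 19284 genes with reads, except female 3 of the treated APP/PS1 group, which held 0.913 M reads on 9509 genes. Each of the 4 comparisons had its own table of 12 libraries, normalized on its own. Values are normalized counts or log2 fold changes with n = 6 libraries per group unless another n is given, and levels set side by side across tables are CPM (counts per M reads) computed from recovered reads.

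The first comparison, old against young, asked what changed in the hippocampus between 8 and 18 months. Other differences between the cohorts of mice cannot be told apart from age here. Ide, which encodes the insulin-degrading enzyme that also degrades amyloid beta, rose 1.97-fold, from 2093 ± 102 in young to 4127 ± 118 normalized counts in old mice (mean ± SD, n = 6 each; adjusted p = 9.45e-07). Fgfbp3, a fibroblast growth factor binding protein, rose 2.14-fold from 209 ± 21.3 to 447 ± 45.2 (adjusted p = 0.00102). The microglial lipid receptor Trem2 rose 1.70-fold from 423 ± 22.6 to 724 ± 102 (adjusted p = 0.01001), and Pld4, a phospholipase D family member found in microglia, rose 1.59-fold from 413 ± 21.8 to 661 ± 86.7 (adjusted p = 0.0243). Gpr17, a receptor of cells committed to become oligodendrocytes, fell to 0.657 of its young level, from 2257 ± 183 to 1490 ± 200 (adjusted p = 0.00159). For Ide, Fgfbp3, Trem2, Pld4 and Gpr17 the 6 old libraries did not overlap the 6 young ones. The sixth called gene, 4931408D14Rik, rose from 15.8 ± 6.19 to 87.4 ± 13.3 and is named here after its values were seen, since the rule for named genes left it out. Nfkb1 and Nlrp3 did not pass: Nfkb1 had a log2 fold change of -0.02 (95% limits -0.19 and 0.15, adjusted p = 0.980) and Nlrp3 one of -0.25 (95% limits -0.88 and 0.37, adjusted p = 0.916).

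On GRCm38, with 1-based coordinates of the annotation, Ide lies on chromosome 19 from 37268743 to 37337852 and Fgfbp3 on the same chromosome from 36917550 to 36919615. Trem2 lies on chromosome 17 from 48346401 to 48354147, Pld4 on chromosome 12 from 112760655 to 112768990 and Gpr17 on chromosome 18 from 31942997 to 31949636. All 5 are annotated as protein-coding, and the counts are over each gene.

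**Figure D1:**
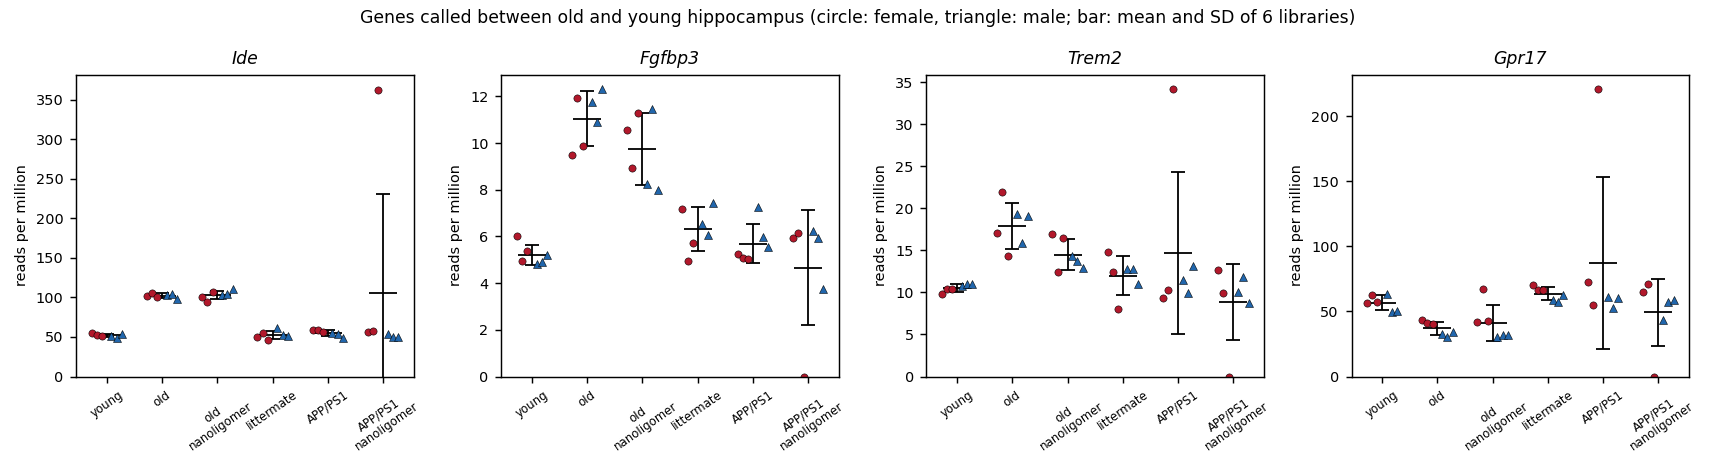
CPM of Ide, Fgfbp3, Trem2 and Gpr17 in each of the 36 libraries by group, with circles for females, triangles for males and bars for the mean and SD of 6 libraries. Apart from APP/PS1 nanoligomer female 3, the 12 libraries of mice of 18 months hold at least 94.1 CPM of Ide and the others at most 60.9.

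Interferon-stimulated genes had higher estimates in old mice throughout the list: all 44 measured members were positive, with a median log2 fold change of 1.04. Oas2, an antiviral synthetase, had a log2 fold change of 1.44 ± 0.277 (SE) and Ifitm3, a restriction factor of viral entry, one of 1.04 ± 0.209 (adjusted p = 0.202 for both). 34 of the 44 passed when adjusted over the list alone, and 0 over all genes in limma, with 36 at an unadjusted p under 0.05, 0 in edgeR and 15 in DESeq2. Among MHC class I and antigen processing genes 19 of 20 estimates were positive with a median of 0.74, and H2-Q6 and H2-Q7 stood at 1.72 ± 0.336 and 2.15 ± 0.467. 13 of them passed adjusted over the list alone and 0 over all genes in limma, with 15 at an unadjusted p under 0.05, 0 in edgeR and 9 in DESeq2. Camera placed both lists above other genes (adjusted p = 2.55e-38 and 5.92e-19), and neither call held, with adjusted p = 0.0907 with an estimated correlation for each.

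Genes of disease-associated microglia were positive for 26 of 29 members with a median log2 fold change of 0.36. Trem2 alone passed over all genes, 12 passed adjusted over the list alone, and DESeq2 called 7. Homeostatic microglia markers were positive for 18 of 19 with a median of 0.27, and Olfml3 had a log2 fold change of 0.36 ± 0.0904. For these markers 5 passed adjusted over the list alone and 0 over all genes in limma, with 10 at an unadjusted p under 0.05, 0 in edgeR and 2 in DESeq2. Complement genes were positive for 17 of 21 with a median of 0.38, and 2 chains of C1q, the initiator of the classical pathway, had the smallest p: C1qa at 0.71 ± 0.112 (adjusted p = 0.0775) and C1qb at 0.65 ± 0.106 (adjusted p = 0.0798). 7 complement genes passed adjusted over the list alone and 0 over all genes in limma, with 0 in edgeR and 5 in DESeq2. At an unadjusted p under 0.05 in limma there were 10, 8 higher and 2 lower. NF-kB induced cytokines and adhesion genes were positive for 14 of 16 with a median of 0.42, and the chemokines Ccl3 and Cxcl10 stood at 1.17 ± 0.282 and 2.94 ± 0.720. 4 of these passed adjusted over the list alone and 0 over all genes in limma, with 6 at an unadjusted p under 0.05, 0 in edgeR and 3 in DESeq2. Camera called all 4 lists in the positive direction, and none held with an estimated correlation, each with adjusted p = 0.0907.

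Inflammasome and pyroptosis genes were positive for 15 of 19 with a median log2 fold change of 0.21 and were called by camera (adjusted p = 0.00239; adjusted p = 0.392 with an estimated correlation). The adaptor Pycard stood at 0.63 ± 0.160 and Naip2 at 0.84 ± 0.225, and these 2 passed adjusted over the list alone. Over all genes 0 inflammasome genes passed in limma, with 0 in edgeR and 1 in DESeq2. At an unadjusted p under 0.05 in limma there were 6, 5 higher and 1 lower. The list of NF-kB subunits and regulators missed the threshold of camera (adjusted p = 0.0561), with 16 of 27 estimates positive and a median of 0.01. MHC class II genes were positive for 9 of 10 with a median of 0.59, and reactive astrocyte genes for 23 of 30 with a median of 0.33. The complement component C4b stood at 1.69 ± 0.402 among the latter. Both lists were called, with adjusted p = 0.391 and 0.367 with an estimated correlation.

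All 22 choroid plexus markers had negative estimates, with a median log2 fold change of -1.79, and Kcne2 stood at -3.14 ± 1.02 and Car12 at -0.78 ± 0.260. All 14 ependymal markers (median -0.72) and all 16 striatum markers (median -0.61) were negative, as were 15 of 17 thalamus and habenula markers (median -0.28). Camera called these 4 lists in the negative direction, with adjusted p = 0.367, 0.472, 0.480 and 0.639 with an estimated correlation. Ttr, the transthyretin gene of the choroid plexus, ranged from 5.37 to 3747 CPM among the young libraries and from 12.2 to 184 among the old ones. Genes of oligodendrocyte precursors and newly formed oligodendrocytes were negative for 17 of 22 with a median of -0.09 (adjusted p = 0.531 with an estimated correlation), and Gpr17 alone passed over all genes. Neurogenesis and proliferation genes were negative for 20 of 30 with a median of -0.13, and Sox11 stood at -0.38 ± 0.119 (adjusted p for the list = 0.0907 with an estimated correlation). Myelinating oligodendrocyte genes were positive for 28 of 30 with a median of 0.19, and Apod stood at 0.57 ± 0.174 (adjusted p = 0.540 with an estimated correlation).

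Camera called 6 further lists with age. Cytosolic ribosomal protein genes were positive for 76 of 80 (median 0.06), nuclear oxidative phosphorylation genes for 49 of 73 (median 0.02) and immediate early genes for 28 of 35 (median 0.29), with adjusted p = 0.505, 0.708 and 0.507 with an estimated correlation. Glucocorticoid-induced genes were positive for 21 of 25 (median 0.16) and stress genes of the endoplasmic reticulum negative for 24 of 34 (median -0.07), with adjusted p = 0.0907 and 0.474 with an estimated correlation. The sex-linked control genes were positive for 6 of 6, with Eif2s3y at 1.44 ± 0.673 (adjusted p for the list = 0.203 with an estimated correlation). Females of the aging arm held at most 0.392 CPM of Eif2s3y and males 23.4 to 37.9, so values near the floor enter this estimate.

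By limma 6 of 16626 genes were called between old and young, 5 higher and 1 lower, and 1020 had an unadjusted p under 0.05 where 831 would be expected by chance. edgeR called the same 6, and DESeq2 called 123, the 6 among them. Camera called 22 of 45 lists, 15 higher and 7 lower; 0 held with an estimated correlation and fry called 1, the list of disease-associated microglia genes (adjusted p = 0.0206). The effect was tested within each sex: Ide passed in females, and Ide, Fgfbp3 and Gpr17 in males. The sex difference itself was called for 0 genes in limma, with 730 at an unadjusted p under 0.05 and 21 called in DESeq2. With the scores of choroid plexus, striatum and thalamus markers as covariates, a choice made after seeing the data, 1 gene was called, and without old female 1 the count was 11. Under these covariates the estimates of Fgfbp3, Trem2 and Pld4 stood at 1.04 ± 0.197, 0.77 ± 0.198 and 0.67 ± 0.189, against 1.09 ± 0.102, 0.76 ± 0.0949 and 0.67 ± 0.0922 without them. Gpr17 stood at -0.50 ± 0.0955 against -0.61 ± 0.0622. These calls ended with the larger SE, and for Gpr17 with a smaller estimate too. With 1 library left out at a time the call of Pld4 ended in 10 of 12 fits (adjusted p = 0.0629 to 0.107) and that of Trem2 in 1 (adjusted p = 0.0513). The estimates stayed between 0.61 and 0.73 for Pld4, with SE up to 0.101, and between 0.69 and 0.82 for Trem2. With the replicate labels as a block the calls of Fgfbp3, Trem2, Pld4 and Gpr17 ended at the same estimates, with SE of 0.12, 0.0988, 0.0797 and 0.0716 and adjusted p = 0.0527, 0.0831, 0.0527 and 0.0527. The SE was larger than without the block for all but Pld4.

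The comparison of old nanoligomer mice with old mice asked what the treatment changed at 18 months, and no gene passed in limma. The genes with the smallest p were Hgf, the hepatocyte growth factor, at a log2 fold change of 0.69 ± 0.131 (SE; 100 ± 12.1 in old and 163 ± 22.4 in treated mice, n = 6 each), the acid ceramidase gene Asah1 at 0.33 ± 0.0717, the Wnt inhibitor Apcdd1 at -0.43 ± 0.0939 and the stress-responsive mTOR inhibitor Ddit4 at -0.39 ± 0.0863, each with adjusted p = 0.678. Arhgap25 stood at 0.63 ± 0.143, Rabep1 at 0.20 ± 0.0475, Snhg18 at -0.77 ± 0.177 and Bcar1 at -0.24 ± 0.0580. Nfkb1, which encodes an NF-kB subunit, held 783 ± 48.5 normalized counts in old and 739 ± 87.8 in treated mice, a log2 fold change of -0.09 with 95% limits of -0.29 and 0.11. Nlrp3 held 54.6 ± 21.3 and 59.7 ± 21.7, a log2 fold change of 0.16 with 95% limits of -0.47 and 0.79. Ide and Fgfbp3, which differed with age, stood at 0.01 ± 0.0503 and -0.20 ± 0.116 between treated and untreated old mice.

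All 44 interferon-stimulated genes had lower estimates in treated than in untreated old mice, with a median log2 fold change of -0.63. Zbp1, a nucleic acid sensor, stood at -2.43 ± 0.595 and Irf7, a transcription factor of the interferon response, at -1.43 ± 0.405. Camera called the list (adjusted p = 1.05e-16; adjusted p = 0.562 with an estimated correlation). 0 members passed adjusted over the list alone or over all genes in limma, with 21 at an unadjusted p under 0.05, 0 in edgeR and 1, Zbp1, in DESeq2. MHC class I and antigen processing genes were negative for 18 of 20 with a median of -0.35, and H2-Q7 and H2-Q4 stood at -1.10 ± 0.337 and -0.87 ± 0.271. NF-kB induced cytokines and adhesion genes were negative for 15 of 18 (median -0.43), with Ccl3 at -1.41 ± 0.557 (-0.94 without treated old female 2) and Csf1 at -0.38 ± 0.152. Disease-associated microglia genes were negative for 23 of 30 (median -0.14), with Cst7 at -1.34 ± 0.467 and Itgax at -1.20 ± 0.424. Old female 2 stood apart as the highest untreated old library for this list, and without it Itgax stood at -0.94. These 3 lists were called by camera, each with adjusted p = 0.562 with an estimated correlation.

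Camera also called 6 further lists in the negative direction beside the sex-linked genes. Meningeal and perivascular fibroblast markers were negative for 20 of 21 (median -0.42), with Bgn at -0.44 ± 0.149 and Serpinf1 at -0.50 ± 0.171. Myelinating oligodendrocyte genes were negative for 27 of 30 (median -0.21), reactive astrocyte genes for 26 of 30 (median -0.29), complement genes for 16 of 21 (median -0.17) and MHC class II genes for 8 of 10 (median -0.60). The adjusted p of these 5 lists with an estimated correlation was 0.562, 0.674, 0.610, 0.640 and 0.670. Dentate gyrus granule cell markers were negative for 14 of 17 (median -0.27; adjusted p = 0.619 with an estimated correlation), and Fam163b, at -0.49 ± 0.122, passed adjusted over the list alone. Sex-linked control genes were negative for 6 of 6, with Eif2s3y at -1.41 ± 0.646 (adjusted p = 0.562 with an estimated correlation). Females near the floor, at most 0.392 CPM of Eif2s3y in this arm, enter this estimate too.

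Lists called in the positive direction were led by cytosolic ribosomal protein genes, positive for 71 of 80 with a median log2 fold change of 0.08, where Rps27a stood at 0.24 ± 0.0751 and Rpl36a at 0.21 ± 0.0707 (adjusted p = 0.670 with an estimated correlation). Neocortex markers were positive for 16 of 20 (median 0.28), striatum markers for 13 of 16 (median 0.58), neuropeptide genes for 15 of 23 (median 0.20) and GABAergic interneuron genes for 23 of 29 (median 0.10). With an estimated correlation their adjusted p was 0.610, 0.782, 0.674 and 0.562. Stress genes of the endoplasmic reticulum were positive for 22 of 34 (median 0.08; adjusted p = 0.562 with an estimated correlation), and Manf, a secreted stress protein, passed adjusted over the list alone at 0.27 ± 0.0653. Neither the list of NF-kB subunits and regulators (19 of 27 negative, median -0.08, adjusted p = 0.229) nor that of inflammasome and pyroptosis genes (12 of 20 negative, median -0.14, adjusted p = 0.131) was called. Homeostatic microglia markers were not called (adjusted p = 0.421), and their median was 0.03 where their mean was -0.05.

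**Figure D2:**
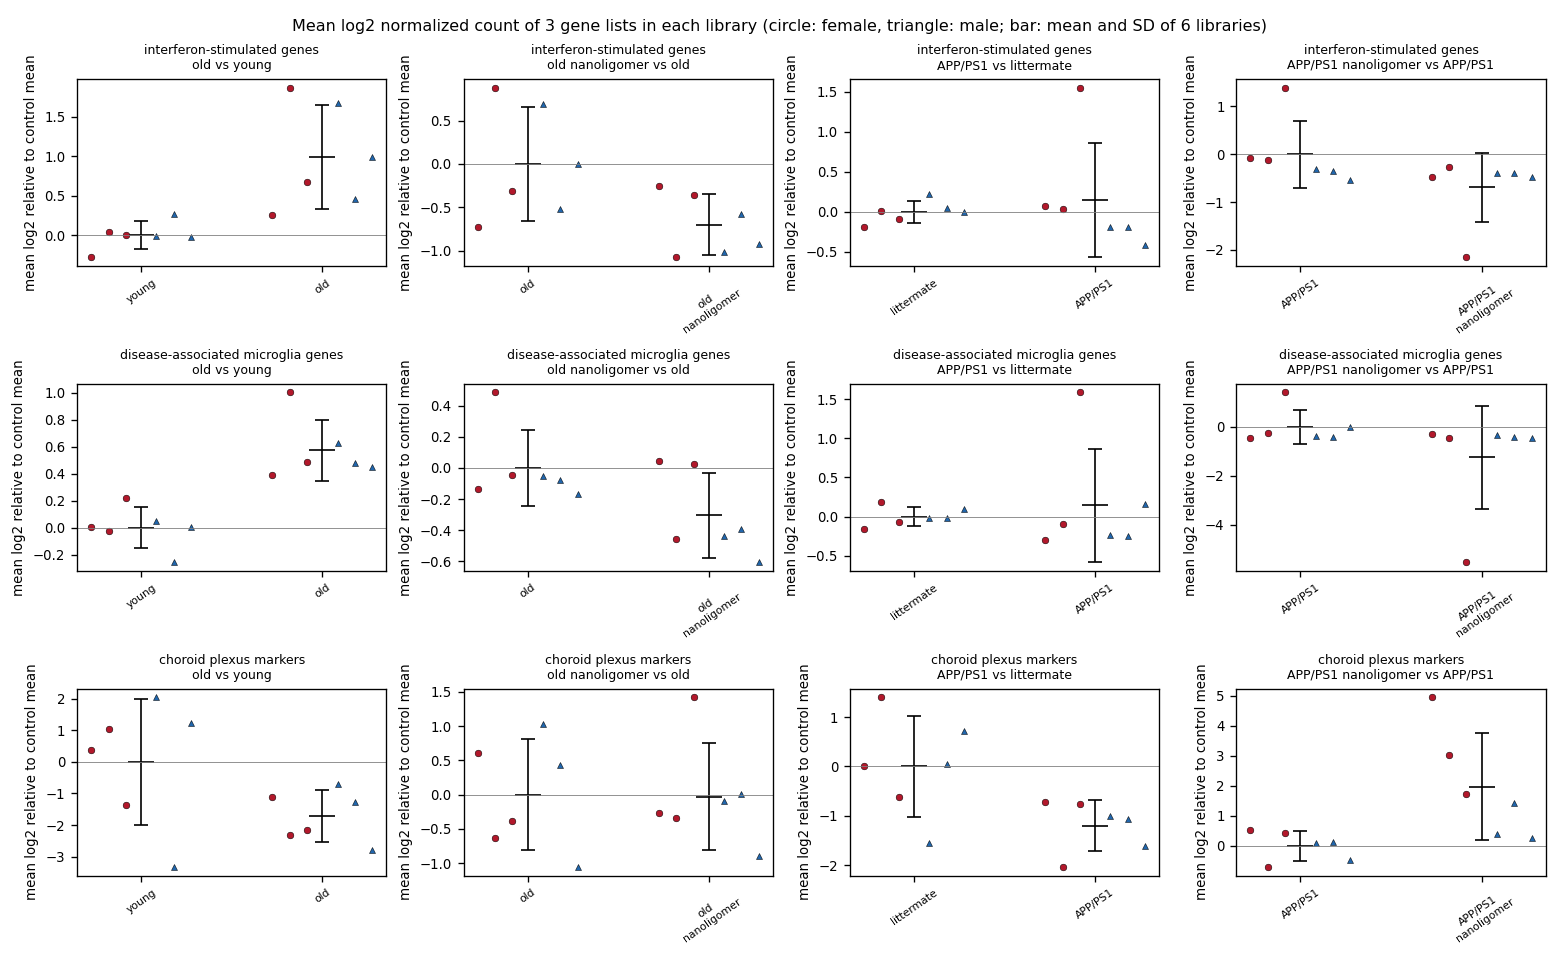
Mean log2 normalized count of interferon-stimulated genes, disease-associated microglia genes and choroid plexus markers per library, relative to the mean of the first group of each comparison, with circles for females, triangles for males and bars for the mean and SD of 6 libraries. Each column has its own axes, and APP/PS1 nanoligomer female 3 is the lowest point of the fourth column for the first 2 lists.

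Between treated and untreated old mice limma called 0 of 16517 genes, with 1192 at an unadjusted p under 0.05 where 826 would be expected by chance, and edgeR called 0. DESeq2 called 2, Hgf higher and Zbp1 lower. Camera called 17 of 45 lists, 6 higher and 11 lower, of which 0 held with an estimated correlation; fry called 0. The sex difference was called for 0 genes in limma, with 778 at an unadjusted p under 0.05 and 3 in DESeq2.

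The comparison of APP/PS1 mice with non-carrier littermates at 4 months asked what the transgenes changed. App, which encodes the amyloid precursor protein, rose 2.11-fold, from 62218 ± 2265 to 132970 ± 23316 normalized counts (mean ± SD, n = 6 each; adjusted p = 0.00162). Prnp, the prion protein gene whose promoter drives the transgenes of some APP/PS1 lines, rose 2.32-fold (log2 fold change 1.22 ± 0.130 SE, adjusted p = 0.00176). Prn, annotated over the same part of chromosome 2, rose 1.97-fold (log2 fold change 0.98 ± 0.0865, adjusted p = 0.000392), and reads shared between Prn and Prnp cannot be separated here. The adhesion gene Cdh22 rose by a log2 fold change of 0.77 ± 0.0906 and Gabra3, a GABA-A receptor subunit, by 0.64 ± 0.0756 (adjusted p = 0.00340 for both). Brinp3 rose by 0.81 ± 0.115 (adjusted p = 0.0203) and Sema3a, an axon guidance signal, by 1.10 ± 0.163 (adjusted p = 0.0286). Thy1, whose promoter drives other amyloid transgenes, did not pass, with a log2 fold change of 0.05 ± 0.0885 (adjusted p = 0.892). Nfkb1 stood at 0.05 (95% limits -0.17 and 0.27) and Nlrp3 at 0.37 (95% limits -0.23 and 0.97), and neither passed. For each of the 8 called genes the 6 APP/PS1 libraries stood above all 6 littermate libraries.

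App lies on chromosome 16 from 84949685 to 85173766, and Prnp on chromosome 2 from 131909928 to 131938429, overlapping Prn, from 131909957 to 131956130. Cdh22 lies on chromosome 2 from 165111507 to 165234853, Gabra3 on chromosome X from 72432681 to 72656848, Brinp3 on chromosome 1 from 146494760 to 146902472 and Sema3a on chromosome 5 from 13125414 to 13602565. The counts on App do not separate reads of the transgenes from reads of the mouse genes.

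**Figure D3:**
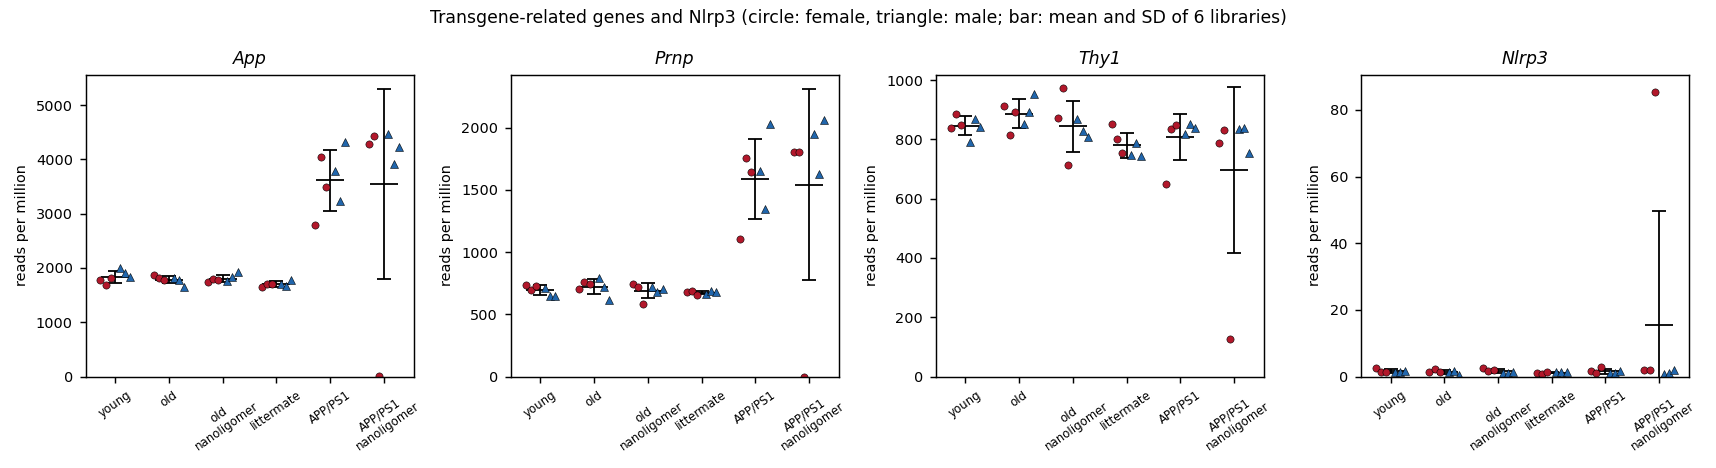
CPM of App, Prnp, Thy1 and Nlrp3 in each of the 36 libraries by group, with circles for females, triangles for males and bars for the mean and SD of 6 libraries. APP/PS1 nanoligomer female 3 holds 5.48 CPM of App and 85.4 of Nlrp3.

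All 21 meningeal and perivascular fibroblast markers had lower estimates in APP/PS1 mice, with a median log2 fold change of -0.75, and Igf2, an insulin-like growth factor made by leptomeninges, stood at -1.06 ± 0.222 and Ogn at -1.21 ± 0.290. 7 of them passed adjusted over the list alone and 0 over all genes in limma, with 11 at an unadjusted p under 0.05, 0 in edgeR and 4 in DESeq2. Choroid plexus markers were negative for 20 of 21 with a median of -1.02, and Msx1 and Slc13a4 stood at -1.29 ± 0.372 and -1.32 ± 0.411. 10 of these passed adjusted over the list alone and 0 over all genes in limma, with 10 at an unadjusted p under 0.05, 0 in edgeR and 5 in DESeq2. Camera called both lists, with adjusted p = 0.308 with an estimated correlation for each. Haemoglobin genes were negative for 7 of 7 (median -0.46; adjusted p = 0.374 with an estimated correlation) and MHC class II genes for 8 of 10 (median -0.47; adjusted p = 0.515 with an estimated correlation).

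Striatum markers were positive for 16 of 16 between APP/PS1 mice and littermates with a median log2 fold change of 1.20, and Penk, an opioid peptide precursor, stood at 1.80 ± 0.460 and Sh3rf2 at 2.14 ± 0.650 (adjusted p for the list = 0.466 with an estimated correlation). Neuropeptide genes were positive for 20 of 24 (median 0.68), with Vgf at 0.38 ± 0.0713 and Adcyap1 at 1.01 ± 0.209. Penk belongs to both the striatum and the neuropeptide list, so these are not separate results. Neocortex markers were positive for 15 of 20 (median 0.43), with Rasgrf2 at 0.58 ± 0.105 and Nxph4 at 1.19 ± 0.283. Cholesterol synthesis genes were positive for 22 of 24 (median 0.15), with the squalene synthase gene Fdft1 at 0.26 ± 0.0620. These 3 lists were called by camera, each with adjusted p = 0.279 with an estimated correlation. Dentate gyrus granule cell markers were negative for 13 of 17 (median -0.36), with Prox1 at -0.89 ± 0.244, and CA3 and CA2 pyramidal markers for 12 of 18 (median -0.31), with Nrip3 at -0.46 ± 0.107 and Coch at 0.93 ± 0.267. Their adjusted p with an estimated correlation was 0.358 and 0.308. Immediate early genes were negative for 28 of 35 (median -0.37), with Klf2 at -0.74 ± 0.187 (adjusted p = 0.569 with an estimated correlation). APP/PS1 female 1 stood apart in these lists, with the highest striatum and neuropeptide scores and the lowest immediate early score of its group; without it Penk stood at 1.33 and Sh3rf2 at 1.52.

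Nuclear oxidative phosphorylation genes were negative for 55 of 73 (median log2 fold change -0.07), ribosomal protein genes for 61 of 80 (median -0.04) and glucocorticoid-induced genes for 21 of 24 (median -0.13), with adjusted p = 0.763, 0.859 and 0.466 with an estimated correlation. Camera did not call disease-associated microglia genes (adjusted p = 0.459), reactive astrocyte genes (adjusted p = 0.254), interferon-stimulated genes (adjusted p = 0.0947), NF-kB induced cytokines and adhesion genes (adjusted p = 0.911), inflammasome genes (adjusted p = 0.324) or NF-kB subunits and regulators (adjusted p = 0.795). APP/PS1 female 3 stood apart in glial transcripts: it held 2095 CPM of the astrocyte filament gene Gfap, 34.2 of Trem2 and 221 of Gpr17, against at most 344, 13.1 and 72.9 in the other 5 APP/PS1 libraries.

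Between APP/PS1 mice and littermates limma called 8 of 16475 genes, all higher, and 1677 had an unadjusted p under 0.05 where 824 would be expected by chance. edgeR called the same 8, and DESeq2 called 253, 149 higher and 104 lower, the 8 among them. Limma with array weights called 548, 297 higher and 251 lower. Camera called 14 of 45 lists, 4 higher and 10 lower, of which 0 held with an estimated correlation; fry called 1, the amyloid processing and clearance genes (adjusted p = 0.00573), which camera did not call. With 1 library left out at a time the call of Sema3a ended in 10 of 12 fits (adjusted p = 0.0541 to 0.133) and that of Brinp3 in 7 (adjusted p up to 0.0928). The estimates stayed between 1.005 and 1.24 for Sema3a, with SE up to 0.179, and between 0.74 and 0.89 for Brinp3. Within females 1 gene passed and within males 6, App, Gabra3, Prn, Prnp and Rasgef1c among these. The sex difference was called for 0 genes in limma, with 840 at an unadjusted p under 0.05 and 0 in DESeq2. Without APP/PS1 female 2 limma called it for 158.

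Without APP/PS1 female 3, a choice made after seeing the data, limma called 256 genes, 129 higher and 127 lower, with all 8 kept (n = 5 and 6). The neocortex markers Rasgrf2 and Foxp2 then rose by a log2 fold change of 0.68 ± 0.0745 and 1.99 ± 0.256, and the CA3 marker Nrip3 fell by 0.56 ± 0.0754. Klf2 fell by 0.89 ± 0.149 and the collagen-binding Lum by 1.24 ± 0.212. 2 of 22 called lists then held with an estimated correlation, neocortex markers, positive for 16 of 20 with a median of 0.47, and reactive astrocyte genes (adjusted p = 0.0419 each). Camera then also called disease-associated microglia genes (median -0.15, against 0.12 with all libraries) and inflammasome genes (median -0.05) in the negative direction, with adjusted p = 0.0457 and 0.0475. With an estimated correlation these were 0.534 and 0.201. The library was left out after its values were seen: it held by far the most Gfap and the lowest Rasgrf2 of its group. The gene and list calls gained here rest on that choice and are not counted as results. With all libraries the median of reactive astrocyte genes was -0.10. Without APP/PS1 female 3 only the real split of 100 gave as many as 256 genes (highest other 169), but these splits do not undo that choice. Foxp2 and Lum were chosen after their values were seen. Without APP/PS1 female 1 the count was 21 genes.

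The comparison of treated with untreated APP/PS1 mice asked what the nanoligomer changed at 4 months, and no gene passed in limma. With treated female 3 left out, a choice made after seeing its depth (n = 5 and 6), App held 100230 ± 17857 normalized counts in untreated and 119580 ± 5276 in treated mice, a log2 fold change of 0.26 ± 0.131 (SE). Prnp stood at 0.25 ± 0.150 and Thy1 at 0.02 ± 0.0924. Nfkb1 stood at -0.06 (95% limits -0.30 and 0.19) and Nlrp3 at 0.00 (95% limits -0.73 and 0.73). With that library included the estimates were -1.44 ± 1.57 for App, -2.34 ± 2.39 for Prnp, -0.53 ± 0.525 for Thy1, -1.59 ± 1.44 for Nfkb1 and 0.83 ± 0.855 for Nlrp3, each with adjusted p = 0.578.

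Choroid plexus markers stood higher in treated than in untreated APP/PS1 libraries: without treated female 3 all 22 estimates were positive with a median log2 fold change of 2.34. The same untreated libraries stood below littermates for 20 of 21 of these markers (median -1.02). Both differences thus use the untreated libraries with opposite sign, and the source of the difference with treatment was not tested. The bicarbonate transporter gene Slc4a5 stood at 4.31 ± 0.855, Sostdc1 at 2.91 ± 0.752, F5 at 2.41 ± 0.690 and Cldn2 at 3.08 ± 0.981, each with adjusted p = 0.997. 13 of the 22 passed adjusted over the list alone and 0 over all genes in limma; the list was called by camera, with adjusted p = 0.508 with an estimated correlation. DESeq2 called Slc4a5 at 4.68 ± 0.918 (adjusted p = 0.00187) without treated female 3 and at 5.45 ± 0.958 (adjusted p = 3.69e-05) with all libraries, where it called no other of these markers. Ttr, which encodes the thyroid hormone carrier transthyretin of the choroid plexus, ranged from 35.6 to 3521 CPM in these 5 treated libraries and from 6.64 to 28.8 in the untreated ones. With all 12 libraries 21 of 22 markers were positive with a median of 1.87 (adjusted p = 0.125 with an estimated correlation), and Slc4a5 alone passed adjusted over the list alone.

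With all 12 libraries camera called ribosomal protein genes (77 of 80 negative, median log2 fold change -0.83), neuropeptide genes (22 of 24 negative, median -1.63), myelinating oligodendrocyte genes (29 of 30 negative, median -1.71) and disease-associated microglia genes (26 of 29 negative, median -1.54) in the negative direction. Each of these 4 had adjusted p = 0.925 with an estimated correlation, and the median of all genes was -0.68. Without treated female 3 the median of disease-associated microglia genes was -0.17, with Itgax at -1.88 ± 0.816 and Cst7 at -1.70 ± 1.12, and that of interferon-stimulated genes -0.22, with 34 of 42 negative. Homeostatic microglia markers were then negative for 16 of 19 with a median of -0.19. Camera called these 3 lists, each with adjusted p = 0.797 with an estimated correlation. With APP/PS1 female 3 left out too, a choice made after seeing the data (n = 5 each), camera called none of the 3. Disease-associated microglia genes then had a median of 0.01 (13 of 26 negative, adjusted p = 0.828), interferon-stimulated genes one of -0.11 (adjusted p = 0.0972) and homeostatic markers one of -0.04 (adjusted p = 0.374). Without treated female 3 alone, astrocyte markers were negative for 18 of 20 (median -0.13) and precursor and newly formed oligodendrocyte genes for 19 of 22 (median -0.16), with adjusted p = 0.582 and 0.797 with an estimated correlation. Haemoglobin genes were positive for 7 of 7 (median 0.44), immediate early genes for 30 of 35 (median 0.18) and nuclear oxidative phosphorylation genes for 56 of 73 (median 0.04). Neuropeptide genes were negative for 21 of 24 (median -0.32), reactive astrocyte genes for 25 of 28 (median -0.30) and myelinating oligodendrocyte genes for 27 of 30 (median -0.12). So were neurogenesis and proliferation genes for 23 of 33 (median -0.17), ribosomal protein genes for 57 of 80 (median -0.03) and pericyte and smooth muscle markers for 9 of 15 (median -0.15). Camera called these 9 lists, each with adjusted p = 0.797 with an estimated correlation. With APP/PS1 female 3 left out too, camera no longer called reactive astrocyte genes (median -0.13, adjusted p = 0.359) or neurogenesis and proliferation genes (-0.04, 0.640). Nor did it then call ribosomal protein genes (-0.02, 0.119) or pericyte and smooth muscle markers (-0.10, 0.276). Troap, Cngb1 and Wnt9b, among the genes with the smallest p with all libraries, stood at -2.39 ± 0.757, -2.41 ± 0.761 and -1.96 ± 0.582 without treated female 3.

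Between treated and untreated APP/PS1 mice limma called 0 of 17149 genes with all libraries, with 84 at an unadjusted p under 0.05 where 857 would be expected by chance, and edgeR called 0 and DESeq2 7. Without treated female 3 limma called 0 of 16124, with 477 at an unadjusted p under 0.05, and DESeq2 called 7. Camera called 5 of 45 lists with all libraries and 15 of 44 without that library, 4 higher and 11 lower; 0 held with an estimated correlation in either, and fry called 0. The sex difference was called for 0 genes in limma, with 145 at an unadjusted p under 0.05 and 32 in DESeq2.

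The effects were also compared with one another. The APP/PS1 effect differed from the age effect for 7 of 16300 genes. Among these it was higher for App (difference of log2 fold changes 1.10 ± 0.128 SE), Prnp (1.15 ± 0.150), Prn (0.89 ± 0.131) and Sulf1, an extracellular sulfatase (1.93 ± 0.348), and lower for Ide (-0.90 ± 0.0870) and Fgfbp3 (-1.23 ± 0.149). The nanoligomer effect in APP/PS1 mice differed from that in old mice for 0 of 16055 genes in limma, with 131 at an unadjusted p under 0.05; without treated female 3 this was 0 of 15990 with 695. Across 16431 genes, which are not independent replicates, the fold changes of age and of treatment in old mice had r = -0.399 and a Spearman rho of -0.404. Both use the old libraries with opposite sign. Library deviations dealt anew within sex, which leave no effect, gave a mean r of -0.478 with an SD of 0.200. With 3 of the old libraries in each comparison the mean r was -0.0640. The effects of the transgenes and of treatment in APP/PS1 mice had r = -0.163 against a mean of -0.371 for deviations dealt anew. Without treated female 3 r was -0.480 against -0.487. The 2 nanoligomer effects had r = -0.00978 across 16055 genes and r = 0.0627 without treated female 3. The age and APP/PS1 effects had r = -0.130, against a mean of 0.00610 and an SD of 0.179 for deviations dealt anew. No gene called with age was called with the transgenes, with 0.00245 shared genes expected.

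Sex labels were checked on Xist and on 4 genes of the Y chromosome. Xist, the RNA that silences an X chromosome, held 646 to 992 CPM in females of the aging arm and 297 to 863 in females of the transgenic arm, and at most 10.1 in males. The Y-linked helicase gene Ddx3y held at least 21.95 in males and at most 0.196 in females.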

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

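The test of a response of the mouse to the nanoligomer was chosen after seeing the result, and those of read depth and genomic DNA before. Within each group of 6 libraries the gap between the highest or lowest library and its nearest neighbour was divided by the range of the group, and a share above the 95% critical value of Dixon's test was taken as a far value. Chance gives such a gap in about 1 of 20 groups: 29 of 228 groups had one, where 11.4 would be expected. 8 of the 29 belong to APP/PS1 nanoligomer female 3 and 7 to APP/PS1 female 1.

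APP/PS1 nanoligomer female 3 had the fewest genes with reads of its group (share 0.894). It was lowest for App (0.983), Prnp (0.981), Thy1 (0.942), Nfkb1 (0.963), E330011O21Rik (0.749) and the score of disease-associated microglia genes (0.966), and highest for Nlrp3 (0.778). It held 0 reads of Gfap, Trem2 and Gpr17, while Tcf7l2, a thalamic marker, reached 962 CPM.

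The library APP/PS1 nanoligomer female 3 had a mean correlation of 0.185 with the other 35 libraries. Low read depth alone is argued against, since the other libraries thinned to its number of reads kept a mean correlation of at least 0.942 and 14877 to 15495 genes. A response of this mouse to the nanoligomer stays open: the other 5 treated libraries had a median correlation of 0.983 with the untreated ones, which tells nothing of this mouse. Reads from genomic DNA stay open too: the density of reads on olfactory receptor genes was 0.0812 of that on all genes, against at most 0.000575 in the other libraries, short of the tenth that was set beforehand for this source and above the hundredth set against it. Against this source stand a rho of reads with exon length of 0.378, lower than the 0.543 to 0.568 of the other libraries where a higher one was asked for, and the uneven fall of its 2569 olfactory receptor reads on 55 of 1095 such genes.

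In APP/PS1 female 1 the striatum score (0.739) and the neuropeptide score (0.786) were highest and Thy1 (0.855 in the comparison with littermates and 0.840 in that with treated mice), Prn (0.713) and the immediate early gene score (0.641) lowest, and Cngb1 was highest (0.653). Its Drd2 level was 97.6 CPM against at most 8.39 in the other 5 libraries of its group. In APP/PS1 female 3 Rasgrf2 was lowest (0.712) and the score of disease-associated microglia genes highest (0.753).

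Among young libraries, Nlrp3 was highest in female 1 (0.815) and Cxcl10 lowest there (0.695), and male 1 had the most genes with reads (0.772) and the lowest score of homeostatic microglia markers (0.723). Among old libraries Nlrp3 was lowest in male 3 (0.635 in both tables), Naip2 (0.795) and the score of disease-associated microglia genes (0.816) were highest in female 2, and Bgn was lowest in female 1 (0.683). Nfkb1 was lowest in treated old male 1 (0.763). Among littermates Nlrp3 (0.801) and Ogn (0.631) were lowest in female 2.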

How the results depend on the processing

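Singling out APP/PS1 nanoligomer female 3 or APP/PS1 female 3, the runs that combine these with other alternatives and the tests with marker scores as covariates were chosen after seeing the data; all other alternatives, each library left out in turn among them, were planned. No list call of the 4 comparisons held with an estimated correlation, where the count was 0 in each, and of the called genes that were named none changed direction under any alternative.

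For age, 6 genes became 14 with array weights, 12 higher and 2 lower, 123 in DESeq2, 1 with marker scores as covariates and 1 with the replicate labels as a block. Without old female 1 there were 11, and without young female 1 there were 4; Ide alone of 5 named called genes passed under every alternative. Pld4 also lost its call with equal totals, at 0.65 ± 0.09835 against 0.67 ± 0.0922 (adjusted p = 0.0558). Sex differences with age numbered 1 with array weights, 21 in DESeq2, 2 without old female 1 and 1 without young female 2. In treated old mice DESeq2 gave 2 genes and 3 sex differences, and 1 sex difference appeared without old female 1.

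For the transgenes, 8 genes became 548 with array weights, 297 higher and 251 lower, 253 in DESeq2, 4 with marker scores as covariates, 256 without APP/PS1 female 3 and 21 without APP/PS1 female 1; the lists went from 14 to 22 without APP/PS1 female 3 and 13 without APP/PS1 male 1. 3 of the 7 named called genes passed under every alternative. Under covariates Cdh22 stood at 0.77 ± 0.173 (0.0906 without them), Gabra3 at 0.64 ± 0.137 (0.0756), Brinp3 at 0.86 ± 0.190 (0.115) and Sema3a at 0.90 ± 0.287 against 1.10 ± 0.163; these calls ended with the larger SE, and for Sema3a with a smaller estimate too. With no trend the calls of Sema3a (SE 0.171, adjusted p = 0.102) and Brinp3 (SE 0.117, adjusted p = 0.0704) ended, and with no sex term that of Cdh22 (SE 0.151, adjusted p = 0.162), with the estimates unchanged. Sex differences numbered 158 without APP/PS1 female 2 and 1 without APP/PS1 female 1. For treated APP/PS1 mice 1 gene was called with no filter and 7 in DESeq2, with and without treated female 3, and sex differences in DESeq2 were 32 with it and 24 without. Lists called there were 18 with array weights, 15 without treated female 3, and 8 without APP/PS1 female 1 or APP/PS1 female 2. With treated female 3 left out, 15 lists became 8 with the block, 9 with covariates and 8 with APP/PS1 female 3 left out too, of which 0 held with an estimated correlation. The difference between the APP/PS1 and age effects covered 46 genes with array weights, 31 higher and 15 lower, and 20 without APP/PS1 female 3.

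Of called lists 3 turned direction in 1 of 22 alternatives: thalamus and habenula markers with age (call kept in 14, largest adjusted p = 0.550), striatum markers in treated old mice (18, 0.448) and ribosomal protein genes with the transgenes (17, 0.553).

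Signs of uncalled genes turned in places. Nfkb1 with age stood at 0.0112 under covariates and between -0.0680 (without young male 2) and 0.0249 (without young male 1), and with the transgenes at -0.0637 under covariates and between -0.00706 (without APP/PS1 male 3) and 0.12 (without APP/PS1 male 2). Nlrp3 with age stood between -0.39 (without old male 2) and -0.0177 (without old male 3), and with the transgenes between 0.174 (without APP/PS1 female 3) and 0.480 (without APP/PS1 female 2). Nlrp3 in treated old mice stood at -0.0648 with array weights and between -0.0448 (without old male 3) and 0.33 (without old male 2). Ccl3 there stood between -1.77 (without treated old female 3) and -0.94 (without treated old female 2) and Nfkb1 between -0.119 (without old female 3) and -0.0105 (without treated old male 1). Thy1 with the transgenes stood between 0.02665 (without APP/PS1 female 2) and 0.133 (without APP/PS1 female 1). In treated APP/PS1 mice array weights gave -0.25 for Nlrp3, 0.23 for App, 0.20 for Prnp and 0.00689 for Thy1. Leaving out single treated libraries gave -2.02 (female 2) to 0.26 (female 3) for App, -3.22 (female 1) to 0.25 (female 3) for Prnp and -0.72 (female 2) to 0.0192 (female 3) for Thy1. Without treated female 3 Nlrp3 stood at -0.0132 with equal totals, -0.0403 with no sex term, -0.26 with array weights and -0.0868 with covariates, where Nfkb1 stood at 0.00210, Thy1 at -0.0449 and Cst7 at 0.21.

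Splitting the shared libraries moved the correlations to -0.0640 for age with treatment in old mice and to 0.00752 for the transgenes with treatment. That of the 2 treatments was 0.0167 with a filter of 50 and 0.00451 with edgeR, and -0.0199 with the block when treated female 3 was left out. It was positive without treated old female 2 (0.00566) or male 1 (0.00571), old male 1 (0.0135), APP/PS1 female 1 (0.0110) or female 2 (0.0365), and treated APP/PS1 female 3 (0.0627) or male 3 (0.0171). Its lowest value was -0.0411, without APP/PS1 female 3. Age with the transgenes ranged from -0.205 without old male 3 to 0.0422 without APP/PS1 female 1. Libraries with the same sex and number share only that label: of 6 pairs 1, 0, 1 and 2 correlated above 0.1 in the 4 comparisons, and 3, 1, 4 and 3 correlated best with their own label. With the block Gabra3 in APP/PS1 mice stood at 0.64 ± 0.0894 against 0.64 ± 0.0756 without it, and its call ended with the larger SE (adjusted p = 0.0625).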

Other observations

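The tests of the 3 explanations for Ide and Fgfbp3, of 1 library and of fewer microglia were chosen after seeing the result; those of the spread between libraries and of other splits of the samples were written before. Genes of the Y chromosome differed between the arms of the study in males. The helicase gene Ddx3y held 73.3 ± 3.66 CPM in males of the transgenic arm and 32.8 ± 7.77 in males of the aging arm (mean ± SD, n = 9 each), the histone demethylase genes Kdm5d 46.9 ± 2.97 and 20.2 ± 4.33 and Uty 20.8 ± 1.53 and 9.20 ± 2.09, and the translation factor gene Eif2s3y 76.3 ± 5.42 and 32.3 ± 5.04. For these 4 genes the ranges of the arms did not overlap; age and cohort differ between the arms together, the strain of the transgenic arm is not given, and no test was made. Xist stood at 10.1 CPM in old male 1 and at most 1.31 in the other males.

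Among lists that camera did not call with age, CA1 pyramidal markers were positive for 10 of 11 (median log2 fold change 0.22, adjusted p = 0.0601), and neuropeptide genes were negative for 17 of 24 (median -0.27, adjusted p = 0.0646). Fibroblast markers had a median of 0.05 and a mean of -0.13 with age, and choroid plexus markers a median of 0.10 and a mean of -0.03 in treated old mice, where median and mean differ in sign. Cst7 and Itgax, microglial genes named here after their values were seen, stood at 2.28 ± 0.384 and 1.99 ± 0.389 with age (adjusted p = 0.0852 and 0.202).

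Ide and Fgfbp3, both on chromosome 19, were higher in old than in young libraries. A single unbroken gained segment spanning both is argued against. The median log2 fold change of the 4 genes tested between them was -0.0169 with an SD of 0.237. Of these Btaf1 stood higher, at 0.39 ± 0.108 (SE, adjusted p = 0.470 in limma). A330032B11Rik stood at 0.00308 ± 0.196, Cpeb3 at -0.16 ± 0.0801 and March5 at -0.04 ± 0.0578. Gains that leave out some or all of the genes between were not tested and stay open. Library scaling is argued against, since Ide stood at 0.966 or more on the log2 scale after rescaling. A difference between the cohorts of mice in place of age stays open and cannot be told apart from age here: treated old libraries held 1.97 times the Ide level of young libraries, and all mice of 18 months may share a variant or a colony as well as an age. The biological explanation, age, is untested against this.

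Interferon-stimulated genes stood higher in old than in young libraries and lower in treated than in untreated old ones. Both differences use the same untreated old libraries with opposite sign. In the comparison with young libraries their mean list scores ran from 7.035 to 8.65 (SD 0.658), against an SD of 0.177 in the young. The mean list score differed by 0.99 with age (exact permutation p = 0.005 within sex) and by -0.70 with treatment (exact permutation p = 0.055), so spread between single libraries could account for the difference with treatment. With 400 permutations 0.005 is the smallest two-sided p this test can give. This list had the smallest camera p of the 45 lists in both comparisons, and the permutation p is not adjusted over lists. 1 library as the whole source is argued against, since the smallest difference with 1 library left out was -0.513 (without old female 2). A fall in microglia as large as that of the interferon genes is argued against, as far as homeostatic markers follow cell number. These markers had a median of 0.0267 with an SD of 0.208 and a mean of -0.0479, where interferon genes had a median of -0.63. Disease-associated microglia genes were negative for 23 of 30 and complement genes for 16 of 21. A smaller fall in microglia or a change of their state is therefore not excluded. That the nanoligomer lowers the interferon response stays an untested hypothesis.

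Other splits of the same libraries were drawn, 100 per result with the real one included. Chance is argued against, though not excluded, for the 6 genes called with age (1 split as large, highest other 3). So it is for the 7 that differed between the APP/PS1 and age effects (1 split, highest other 1). Of the splits for the 8 genes called with the transgenes, 3 were as large, the real one included, and the highest other gave 190. Chance is thus argued against less firmly for these 8. It cannot be excluded for the lists, where 14 splits gave as many as the 22 with age (highest other 28), 30 as many as the 17 in treated old mice (highest other 28), 67 as many as the 14 with the transgenes (highest other 28) and 67 as many as the 5 in treated APP/PS1 mice (highest other 11). Calls of lists at the preset correlation are thus common among random splits. For the results of 0 all 100 splits are as large: genes in treated old mice (highest other 0) and in treated APP/PS1 mice (0), the difference of the treatments (0), and sex differences with age (160), in treated old mice (1), with the transgenes (202) and in treated APP/PS1 mice (0). The splits with 190, 160 and 202 genes point to a structure of the samples other than the groups; what these splits share was not tested.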
